A study of Homo sapiens with 11 samples.

How the data were processed

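Gene expression was measured by RNA sequencing in A549 cells, an established human lung adenocarcinoma line, after exposure to the vehicle DMSO or to cigarette smoke condensate (CSC, the particulate fraction of smoke taken up in a solvent) for 48 hours or 2 weeks. Per the labels' protocols, total RNA was depleted of ribosomal RNA with a Ribo-Zero Gold kit, sequenced on an Illumina HiSeq instrument and aligned to the human genome build hg19 with TopHat2 version 2.0.9 through Illumina BaseSpace. The submitters' processing notes also list CASAVA version 1.7.1a5. The quantifier, the gene annotation, the strand setting and the scaling of the library totals are not given in the sources used here.

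For each of the 11 libraries the authors deposited 1 FPKM value (fragments per kilobase of transcript, relative to all mapped fragments) per gene and locus, with a lower and an upper bound, in 25275 lines. They hold 23609 gene symbols, of which 548 stood at more than 1 locus and were summed. One gene whose estimate was marked as failed in 2 libraries was left out. An FPKM is not a count, so no count model was used, and the low values gave no common step from which whole reads could be recovered. The depth in reads is therefore unknown. The width of the deposited bounds, compared over 11914 lines, put the relative depth of 10 libraries between 1 and 1.37 and that of CSC 2 weeks replicate 2 at 2.69. In 299 to 900 lines per library the FPKM lay above its own upper bound, so the bounds served for relative depth alone. An FPKM of 0 can be a failed estimate, and such genes are described as listed at 0.

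Each library was placed in its group by its title. Testing used limma version 3.58.1 in R version 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(FPKM + 0.5), with the FPKM as deposited. The 12506 genes with an FPKM of at least 1 in at least 2 libraries were tested. All 11 libraries entered 1 fit with 4 groups and no block for the replicate number, so that the DMSO group of 2 libraries at 48 hours shared the estimate of spread with the other groups. The contrasts were CSC against DMSO at 48 hours, CSC against DMSO at 2 weeks, the difference between those effects, and 2 weeks against 48 hours in DMSO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are differences of log2(FPKM + 0.5), which understate the change of weakly expressed genes. The groups, tests, gene lists, rule for named genes and most of the other settings below were fixed before the data were examined.

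Fixed gene lists were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 25 lists that had a measured member in each comparison. Of the lists fixed in advance, 1, of mitochondrial genome transcripts, had no measured member and is not analysed here. The tests were repeated with the correlation estimated for each list, and with fry, a rotation test of the list itself. Called members were counted over all genes tested and, separately, adjusted over the list alone.

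Named genes were chosen by a rule. From each CSC comparison it took the 8 largest rises and the 8 largest falls among called genes with a mean FPKM of at least 1 whose CSC libraries all lay on 1 side of the DMSO libraries. From the other contrasts it took the 5 largest each way. From each list it took up to 4 measured members with the smallest p in either CSC comparison. CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, AHR, ARNT and HMOX1 are reported whatever their values. Symbols with the prefixes SNOR, RNU, MIR, SCARNA, RNA5S, RNY and RN7S were kept out of the largest changes, which leaves other short RNAs such as SNAR-E in. One gene that the rule named is not reported here. The few genes named outside this rule were picked after their values were seen, which the text says where they appear.

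The procedure was tested on simulated values for 12346 genes with seeded changes. At 48 hours it recovered 37.3% of changes of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold, with 8 false calls. At 2 weeks it recovered 65.7%, 98.5% and 100%, with 5 false calls. The simulated noise was normal, independent between genes and libraries, and had the same spread per gene in all groups. Changes were seeded only in genes with an average FPKM of at least 2. No library was made to deviate, so these figures are not the power or error rate in the real libraries. Counts, named genes and lists were recomputed, where a setting allows, with pseudocounts of 0.1 and 1, no filter and a filter at an FPKM of 5, 3 other scalings (median of ratios, a common sum, quantile normalization), eBayes without the trend or with robust estimation, library weights, the replicate number as a block, small RNA genes left out, a fit of only the libraries compared, stricter thresholds, and each library left out in turn. Leaving out symbols at several loci and removing a trend of the values on transcript length (lowess, span 0.3) were added after the data were seen, as were the other settings for the lists of the difference of the effects and of time in DMSO. Lists were not recomputed for the settings of eBayes or the stricter thresholds, which concern single genes, and a gene or list that a filter removed has no value there. Transcript lengths came from the GENCODE annotation lifted to GRCh37, matched by symbol for 20497 of the genes and by an older symbol for 1568 more. Coordinates are those of the deposited files, on hg19 and counted from 1. Tables were handled in Python version 3.11.15 with pandas version 2.3.3 and numpy version 2.4.6, and figures were drawn with matplotlib version 3.10.9.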

Results

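The series holds 11 RNA-seq libraries of A549 cells. DMSO-treated cells gave 2 libraries at 48 hours (replicates 2 and 3) and 3 at 2 weeks, and CSC-treated cells gave 3 at each time. The labels give the CSC dose as 20 µM, a molar unit that is not defined for a mixture, so the dose is quoted as written. The title of the series concerns smoking, DNA methylation and enhancers that tobacco smoke can induce, and the libraries ask which transcripts change when lung cells meet the condensate briefly or for long. The FPKM summed to between 338507 and 484053 per library, and between 11742 and 12051 genes reached an FPKM of 1. The nuclear RNAs RMRP and RPPH1 held 12.4% to 17.5% and 4.18% to 8.26% of the summed FPKM. Correlations between libraries lay between 0.958 and 0.991, and 0 pairs of libraries held identical values. Principal components 1 and 2 carried 25.7% and 23.1% of the variance. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

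After 48 hours of CSC, rises were found in CYP1B1 and TIPARP, which the aryl hydrocarbon receptor (AHR), the sensor of polycyclic aromatic compounds in smoke, is known to induce, and in GREM1 and CCL2. CYP1B1, a cytochrome P450 that oxidises such compounds (chromosome 2, positions 38294746 to 38303323), went from an FPKM of 6.39 ± 1.36 (SD, n = 2) in DMSO to 47.1 ± 19.6 (SD, n = 3) in CSC, a log2 change of 2.71 ± 0.29 (SE). TIPARP, an ADP-ribosyltransferase that restrains AHR (chromosome 3, positions 156392205 to 156424557), went from 9.95 ± 2.47 to 47.9 ± 2.49, a log2 change of 2.23 ± 0.15. GREM1, a secreted antagonist of bone morphogenetic proteins (chromosome 15, positions 33010205 to 33026870), rose by 1.72 ± 0.13, and CCL2, a chemokine for monocytes, by 1.83 ± 0.29. The largest fall of a protein-coding gene was that of NR4A1, an immediate early nuclear receptor, from 7.98 ± 2.14 to 1.67 ± 0.41, a log2 change of -1.96 ± 0.20.

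Adjusted p-values (limma, Benjamini-Hochberg) at 48 hours were 0.00103 for CYP1B1, 1.44e-05 for TIPARP, 3.34e-05 for GREM1, 0.0197 for CCL2 and 6.43e-04 for NR4A1. ALDH1A3, which makes retinoic acid, rose by 1.02 ± 0.13 (adjusted p = 0.00617) and the membrane protein gene TMEM156 by 1.10 ± 0.20 (0.0460). Falls were also found in NPTX1, a secreted neuronal pentraxin (-1.87 ± 0.31, adjusted p = 0.0220), PDE3A, a cyclic nucleotide phosphodiesterase (-1.49 ± 0.21, 0.0110), SUSD2 (-1.46 ± 0.23, 0.0189), RTN4RL2, a Nogo receptor relative (-1.36 ± 0.13, 4.98e-04), the sugar transporter gene SLC45A4 (-1.33 ± 0.14, 6.44e-04) and C1QTNF6 (-1.21 ± 0.19, 0.0189). HNRNPA1P10 (4.39 ± 0.80, 0.0443) and EIF3CL (2.02 ± 0.35, 0.0328) also passed, but a pseudogene and a near-identical copy share reads with their parent genes and are uncertain. SNAR-E, a short RNA with many near-identical copies, stood at 22.5 and 20.6 in the DMSO libraries of 48 hours and was listed at 0 in the other 9, so no fold is given.

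In all, 13 genes rose and 23 fell at 48 hours, of 12506 tested, and 1062 genes had an unadjusted p under 0.05. Every tested gene has this group of 2 DMSO libraries behind it, and the counts moved with single libraries, from 5 higher and 6 lower without DMSO 48 hours replicate 3 to 22 higher and 76 lower without CSC 48 hours replicate 3. Without DMSO 48 hours replicate 2, 9 genes were lower, and without CSC 2 weeks replicate 3 or DMSO 2 weeks replicate 2, 8 were higher. Nearly all calls ended in a fit of only the 5 libraries compared, with 2 higher and 1 lower, where the spread is estimated from fewer samples. Without a filter 13 were lower, and the counts were 20 and 35 under median-of-ratios scaling and 31 and 44 under quantile normalization. Of the 16 largest changes, CYP1B1, TIPARP, GREM1, NR4A1, RTN4RL2 and SLC45A4 stayed past the threshold in each of the 11 fits with 1 library left out. SNAR-E did so in 9, and without either DMSO library of 48 hours it had a single library above an FPKM of 1 and was not tested. Without DMSO 48 hours replicate 3 the adjusted p was 0.151 for CCL2, 0.108 for ALDH1A3, 0.146 for PDE3A, 0.237 for SUSD2, 0.221 for C1QTNF6, 0.255 for HNRNPA1P10 and 0.299 for EIF3CL. Without DMSO 48 hours replicate 2 it was 0.298 for TMEM156 and 0.194 for NPTX1.

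Of 18 measured genes in the list of AHR-responsive xenobiotic genes, 2 rose over all genes tested (TIPARP and CYP1B1) and 6 rose adjusted over the list alone. The list moved up by camera (median log2 change 0.13, adjusted p = 2.48e-04), but not with an estimated correlation (adjusted p = 0.756 with an estimated correlation) and not without CSC 48 hours replicate 3 (adjusted p = 0.0525). With fry its adjusted p was 0.393. CYP1A1, the classical AHR target (chromosome 15, positions 75011883 to 75017877), went from 0.0780 ± 0.0347 to 2.13 ± 1.57 FPKM, with a log2 change of 2.00 ± 0.40 that missed the threshold (adjusted p = 0.0634). AHRR, the AHR repressor (chromosome 5, positions 304291 to 438405), was at 0.553 ± 0.133 and 1.66 ± 0.70 (0.98 ± 0.27, adjusted p = 0.190). Among the 12 measured genes of the AHR receptor complex 0 were called by limma over all genes, and 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.396). AHR itself had a change of -0.46 ± 0.12 (adjusted p = 0.178), its partner ARNT of -0.06 (0.956) and RELB of 0.87 ± 0.19 (0.0823). NQO1 and HMOX1, oxidative stress enzymes that NRF2 can induce, had changes of 0.13 (adjusted p = 0.911) and -0.24 (0.761).

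**Figure D1:**
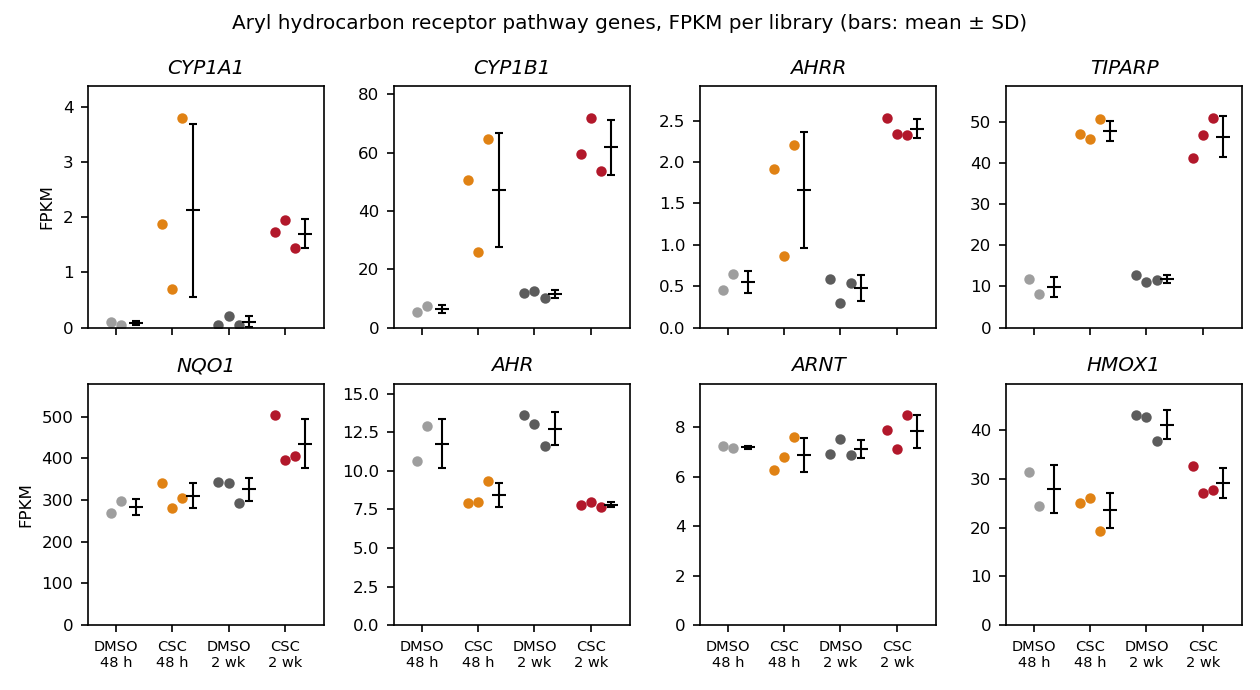
FPKM (linear axis from 0) of 8 genes of the AHR pathway and oxidative stress response in each library, with points for single libraries and bars for the group mean and SD, by treatment (DMSO or CSC) and time (48 hours or 2 weeks). CYP1B1 averages 6.39 and 47.1 FPKM in DMSO and CSC at 48 hours and 11.4 and 61.8 at 2 weeks, TIPARP is at 46.5 or above on average with CSC at both times, and AHR lies lower with CSC at 2 weeks.

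Inflammatory cytokine and chemokine genes moved up as a list at 48 hours by camera (17 measured, median 0.31, adjusted p = 0.0233), with adjusted p = 0.756 with an estimated correlation. CCL2 rose over all genes tested, while 4 members were higher and 2 lower adjusted over the list alone, and BIRC3 had a change of 0.89 ± 0.18 (adjusted p = 0.0604). Genes near CpGs often reported as smoking-associated in blood moved up (17 measured, 2 called, 4 higher and 2 lower adjusted over the list alone, median 0.15, adjusted p = 0.0277, and adjusted p = 0.756 with an estimated correlation). TIPARP and CYP1B1 were its called members and belong to the AHR list too. Cell cycle and proliferation genes moved down (39 measured, 36 negative, median -0.17, adjusted p = 1.04e-04) and replication-dependent histone genes moved up (23 measured, 22 positive, median 0.17, adjusted p = 0.0233). Both had adjusted p = 0.756 with an estimated correlation, and 0 members called by limma over all genes or adjusted over the list alone. CSC 48 hours replicate 3 stood apart in these groups: relative to the mean of the 11 libraries, its list medians were 0.79 for inflammatory genes against 0.23 and 0.20 in the other CSC libraries of 48 hours, and -0.41 for cell cycle genes against -0.02 and -0.00. Without it the adjusted p was 0.279 for the inflammatory list, 0.0913 for the smoking-associated list, 0.910 for cell cycle genes and 0.257 for histones. Without DMSO 48 hours replicate 3 it was 0.269 for the inflammatory list, 0.0989 for the smoking-associated list and 0.388 for histones. The inflammatory list also missed the threshold without CSC 2 weeks replicate 2 (0.0548) and with a common sum of FPKM (0.131), without a filter (0.246), with a filter at an FPKM of 5 (0.0623) and in a fit of only the libraries compared (0.0705). The smoking-associated list did so without CSC 2 weeks replicate 1 (0.0556) or replicate 2 (0.0724), without a filter (0.215), with a filter at an FPKM of 5 (0.333) and with only the libraries compared (0.116). Histones did so without a filter (0.0737). With fry the adjusted p was 0.734 for the inflammatory, cell cycle and histone lists and 0.0976 for the smoking-associated list.

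The other lists did not pass camera at 48 hours. The 15 measured cytosolic heat shock genes all had negative changes (median -0.15, adjusted p = 0.0758), which rest largely on CSC 48 hours replicate 3. Relative to the mean of all libraries their median was -0.73 there, against 0.06 and 0.20 in CSC replicates 1 and 2 and 0.10 and -0.10 in DMSO. HSPA1A, summed over 5 loci and thus uncertain, was at 3.599 FPKM in that library and at 56.5 and 58.4 in the other CSC libraries. The list passed in fits that keep this library, without DMSO 48 hours replicate 3 (0.0185), CSC 48 hours replicate 1 (0.00148) or replicate 2 (4.13e-05), and with a common sum (0.0272), and not without it (0.0913). Mesenchymal and matrix genes had a median of -0.36 (adjusted p = 0.0803) and passed without DMSO 48 hours replicate 3 (8.26e-06) or CSC 48 hours replicate 2 (0.0351), and SPARC in that list had a change of -0.85 (0.0521). NRF2 targets had a median of -0.05 that turned to 0.01 under quantile normalization (adjusted p = 0.449), and passed without DMSO 48 hours replicate 2 (0.0252). The unfolded protein and integrated stress response genes (30 measured, median 0.08, adjusted p = 0.532), p53 targets (23 measured, median 0.09, 0.287), interferon-stimulated genes (14 measured, 0.772) and cytosolic ribosomal protein genes (43 measured, median 0.07, 0.188) held 0 genes called by limma over all genes or adjusted over the list alone. CSC 48 hours replicate 3 stood apart in the stress response list too, with a median of 0.44 against -0.27 and -0.25 in the other CSC libraries. Its members CHAC1 (12.8 FPKM there against 1.36 and 1.98), ASNS (68.2 against 24.5 and 27.2), MTHFD2 (118 against 58.1 and 64.4) and PSAT1 (108 against 58.1 and 64.8) were high in that library alone at 48 hours. The ribosomal list passed without CSC 48 hours replicate 3 (0.0305), with a common sum (0.00973) and under quantile normalization (6.07e-04). Immediate early genes were mixed, with NR4A1 lower, 3 higher and 2 lower adjusted over the list alone, and IER3, which responds to stress, at 0.74 (adjusted p = 0.0663). That list passed camera (main adjusted p = 0.257) without DMSO 48 hours replicate 2 (0.0252) or CSC 48 hours replicate 1 (0.0181).

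At 2 weeks more genes passed the threshold for CSC against DMSO, with 376 higher and 300 lower of 12506 tested. GREM1 rose most, from 4.34 ± 0.27 to 28.7 ± 1.58 FPKM (SD, n = 3 each), a log2 change of 2.59 ± 0.11 (SE). CYP1B1 rose from 11.4 ± 1.34 to 61.8 ± 9.34 (2.38 ± 0.26), TIPARP from 11.8 ± 0.94 to 46.5 ± 4.94 (1.93 ± 0.13) and IGF2, an insulin-like growth factor (chromosome 11, positions 2150347 to 2170833), from 2.39 ± 0.28 to 8.78 ± 0.60 (1.69 ± 0.15). Among the deepest falls were PDE3A, from 14.1 ± 1.21 to 1.55 ± 0.25 (-2.84 ± 0.19; chromosome 12, positions 20522179 to 20837041), RTN4RL2, from 40.7 ± 2.22 to 6.61 ± 0.60 (-2.54 ± 0.12), and IL11, a cytokine linked to fibrosis, from 19.05 ± 1.66 to 3.04 ± 0.43 (-2.47 ± 0.28).

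Adjusted p-values (limma, Benjamini-Hochberg) at 2 weeks were 1.72e-07 for GREM1 and RTN4RL2, 3.04e-04 for CYP1B1, 7.18e-06 for TIPARP, 9.40e-05 for IGF2, 6.93e-06 for PDE3A and 4.36e-04 for IL11. Other large rises were those of CHAC1, a glutathione-degrading enzyme of the stress response (2.25 ± 0.54, adjusted p = 0.0316), STC2, a secreted glycoprotein (1.77 ± 0.45, 0.0416), CDR1 (1.73 ± 0.21, 6.20e-04) and GDF15, a stress-induced cytokine (1.69 ± 0.38, 0.0236). Other large falls were those of DEFB1, an epithelial defensin, from 3.52 ± 0.51 to 0.0511 ± 0.0884 FPKM (-2.87 ± 0.32, 3.71e-04), FGB, the fibrinogen beta chain (-2.54 ± 0.37, 0.00202), NPTX1 (-2.21 ± 0.27, 7.35e-04) and CEACAM6, an epithelial adhesion molecule (-2.18 ± 0.24, 3.14e-04). ANXA8L1 fell by 3.19 ± 0.70 (0.0211), but is a near-identical paralog whose reads cannot be assigned with certainty. Without CSC 2 weeks replicate 3 the adjusted p rose to 0.132 for CHAC1 and 0.103 for GDF15, without DMSO 2 weeks replicate 3 to 0.152 for STC2, and without DMSO 2 weeks replicate 1 to 0.0713 for ANXA8L1. The other 12 of these 16 genes stayed past the threshold in each fit with 1 library left out.

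The counts at 2 weeks depended on single libraries. Without CSC 2 weeks replicate 2, 1310 genes were higher and 534 lower. Leaving out another library of 2 weeks lowered them, to 94 and 180 without CSC 2 weeks replicate 1, 89 and 141 without CSC 2 weeks replicate 3, 129 and 132 without DMSO 2 weeks replicate 1, 111 and 148 without DMSO 2 weeks replicate 2, and 73 and 166 without DMSO 2 weeks replicate 3. Without CSC 48 hours replicate 3, 680 genes were higher, and without a filter 184. With the FPKM as deposited, 55.6% of the called genes were higher, and the median log2 change of all genes was 0.09. Scaling to a common sum moved that median to -0.04 and the share to 34.5% (257 higher, 487 lower), while median-of-ratios scaling gave 38.2% (289 and 468) and quantile normalization 42.4% (325 and 441). Of the 676 calls, 529, 587 and 583 were kept in the same direction under the 3 scalings in that order. Small rises are thus to be read relative to a shift of all genes. The other contrasts shifted likewise under a common sum: the median of all genes moved from 0.09 to -0.02 for time in DMSO and from 0.09 to -0.09 for the difference of the CSC effects. Of 32 tested genes with small RNA type symbols, 2 were called lower, and both are host genes (MIR22HG at -0.80 and MIR31HG at -0.75, picked after their values were seen).

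In the AHR-responsive list, 6 of 18 measured genes rose and 3 fell over all genes tested, against 8 and 5 adjusted over the list alone. The list did not move as a whole by camera (median 0.33, adjusted p = 0.341). Besides TIPARP and CYP1B1, CYP1A1 rose from 0.103 ± 0.099 to 1.71 ± 0.26 FPKM (1.88 ± 0.36, adjusted p = 0.0103) and AHRR from 0.472 ± 0.158 to 2.40 ± 0.12 (1.59 ± 0.24, 0.00231). FOSL2, a subunit of the AP-1 transcription factor, fell by 0.94 ± 0.14 (0.00193). Of members picked after their values were seen, the aldehyde dehydrogenase gene ALDH3A1 rose (1.13 ± 0.29, 0.0405) and the prostaglandin synthase gene PTGS2 fell (-1.44 ± 0.35, 0.0347). AHR fell from 12.7 ± 1.05 to 7.81 ± 0.16 FPKM (-0.67 ± 0.11, 0.00411; chromosome 7, positions 17338276 to 17385775), the only called member of the 12 in its receptor complex over all genes and adjusted over the list alone (camera adjusted p = 0.916). ARNT had a change of 0.13 (0.465) and RELB of 0.12 (0.685). In the smoking-associated CpG list, 5 of 17 rose and 1 fell over all genes, against 8 and 2 adjusted over the list alone (median 0.25, camera adjusted p = 0.211, fry adjusted p = 0.0242). EPAS1, the hypoxia factor HIF-2 alpha, was the member that fell (-0.89 ± 0.12, 9.75e-04), and the peptidase gene ANPEP, picked after its value was seen, rose (0.88 ± 0.15, 0.00660). The CYP1A1 call was lost without DMSO 2 weeks replicate 3 (adjusted p = 0.0506).

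NRF2 targets moved up at 2 weeks by camera (36 measured, median 0.33, adjusted p = 0.00439), with adjusted p = 0.891 with an estimated correlation and 0.129 under quantile normalization. With fry the adjusted p was 0.138. The median was 0.22 under median-of-ratios scaling, 0.18 with a common sum and 0.05 under quantile normalization. Of the 36, 8 rose and 0 fell by limma over all genes, where 376 of the 12506 genes tested rose and 300 fell. Adjusted over the list alone, 15 were higher and 2 lower. The orphan receptor gene NR0B1 rose by 1.28 ± 0.19 (adjusted p = 0.00231), SRXN1, which repairs peroxiredoxins, by 0.62 ± 0.13 (0.0150), the ferritin light chain gene FTL by 0.73 ± 0.17 (0.0316) and the glutathione reductase gene GSR by 0.54 ± 0.13 (0.0316). NQO1 had a change of 0.42 ± 0.14 (0.0909) and HMOX1 of -0.49 ± 0.14 (0.0595). In the list of unfolded protein and integrated stress response genes, 7 of 30 rose, against 8 higher and 1 lower adjusted over the list alone, without a shift of the list (median 0.01, adjusted p = 0.681), and that median turned negative under each of the 3 other scalings (-0.09, -0.13 and -0.08). Members that rose include enzymes that make or handle amino acids: PHGDH (1.42 ± 0.23, adjusted p = 0.00467) and PSAT1 (1.09 ± 0.19, 0.00679) of serine synthesis, the folate enzyme MTHFD2 (1.16 ± 0.22, 0.0105), asparagine synthetase ASNS (1.36 ± 0.29, 0.0172) and CHAC1. STC2 rose as well, and so did the transcription factor gene ATF4, picked after its value was seen (0.75 ± 0.19, 0.0410). Without DMSO 2 weeks replicate 3 the adjusted p rose to 0.0795 for SRXN1, 0.143 for FTL and 0.136 for GSR, and without CSC 2 weeks replicate 3 to 0.0567 for MTHFD2 and 0.0844 for ASNS.

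Inflammatory genes moved down at 2 weeks (17 measured, median -0.36, adjusted p = 3.56e-04, and adjusted p = 0.788 with an estimated correlation). IL11, the neutrophil chemokine CXCL5 (-0.85 ± 0.11, adjusted p = 9.76e-04), CCL2 (-1.06 ± 0.26, 0.0365), PTGS2 and IL18 (picked after its value was seen, -0.57) fell. BIRC3 rose (0.62 ± 0.16, 0.0406), which makes 1 higher and 5 lower over all genes against 1 and 7 adjusted over the list alone. Mesenchymal and matrix genes moved down as well (23 measured, median -0.32, adjusted p = 5.93e-08, and adjusted p = 0.643 with an estimated correlation). Of these 9 fell, against 11 adjusted over the list alone. They include the basement membrane collagen gene COL4A1 (-1.11 ± 0.22, adjusted p = 0.0143), the transcription factor gene SNAI1 (-0.78 ± 0.16, 0.0143), the secreted matrix protein gene TGFBI (820 ± 41.3 to 460 ± 92.2 FPKM, -0.85 ± 0.17, 0.0150). The actin-binding TAGLN, picked after its value was seen, fell too (-2.01 ± 0.41, 0.0151). Epithelial junction and keratin genes moved down too (16 measured, median -0.31, adjusted p = 0.0411, and adjusted p = 0.788 with an estimated correlation), with the claudin gene CLDN2 lower (-1.06 ± 0.23, 0.0192) and 1 higher and 3 lower adjusted over the list alone. This list missed the threshold under median-of-ratios scaling (0.0695), without a filter (0.0991), with the length trend removed (0.0826) and without CSC 48 hours replicate 1 (0.0566), CSC 48 hours replicate 3 (0.0639), DMSO 2 weeks replicate 2 (0.0894) or CSC 2 weeks replicate 3 (0.114). With fry the adjusted p was 0.138 for the inflammatory list, 0.0707 for the mesenchymal list and 0.311 for the epithelial list. Without CSC 2 weeks replicate 3 the adjusted p rose to 0.137 for CCL2, 0.160 for BIRC3, 0.0753 for COL4A1, 0.0838 for TGFBI and 0.1005 for CLDN2, and without DMSO 2 weeks replicate 3 to 0.0726 for SNAI1.

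All 43 cytosolic ribosomal protein genes had positive changes at 2 weeks (median 0.54, adjusted p = 4.68e-16), with adjusted p = 0.788 with an estimated correlation. Over all genes 14 rose, and adjusted over the list alone 43 did. RPS18 went from 580 ± 41.8 to 923 ± 140 FPKM (0.66 ± 0.14, adjusted p = 0.0152), RPLP0 from 637 ± 48.0 to 1044 ± 222 (0.69 ± 0.16, 0.0248), RPL3 changed by 0.66 ± 0.14 (0.0181) and RPL32 by 0.49 ± 0.11 (0.0265). Quantile normalization lowered the list's median to 0.21. Without DMSO 2 weeks replicate 3 the adjusted p of these 4 genes rose to 0.0820, 0.113, 0.0934 and 0.119. All 23 measured replication-dependent histone genes also had positive changes (median 0.56, adjusted p = 7.83e-06, and adjusted p = 0.817 with an estimated correlation), with HIST1H4C called (0.82 ± 0.21, adjusted p = 0.0460, and 0.163 without CSC 2 weeks replicate 3) and 17 higher adjusted over the list alone. Under quantile normalization the histone median was 0.27, and with fry the adjusted p of the histone list was 0.138. The median of the histone list relative to the mean of all libraries was 0.72 and 0.56 in CSC 2 weeks replicates 1 and 3 but -0.13 in replicate 2, close to the DMSO libraries at -0.11, -0.20 and -0.24. For ribosomal protein genes the CSC libraries stood at 0.69, 0.18 and 0.36 and the DMSO libraries at -0.06, -0.02 and -0.25.

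**Figure D2:**
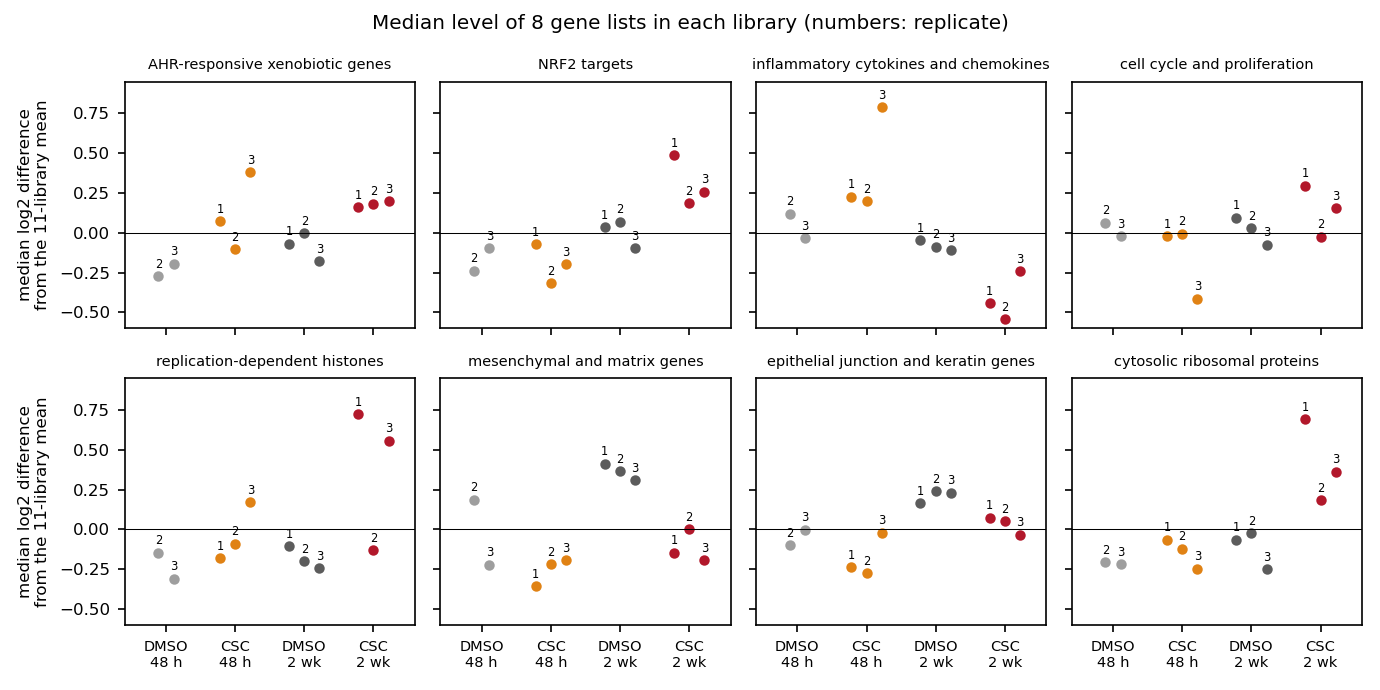
Median log2 difference of the genes of 8 lists from their mean over the 11 libraries (vertical axis) in each library, by treatment and time (horizontal axis), with each point 1 library marked by its replicate number. CSC 48 hours replicate 3 lies apart in the inflammatory (0.79) and cell cycle (-0.41) panels, and CSC 2 weeks replicate 2 lies at -0.13 for histones where the other CSC libraries of 2 weeks are at 0.72 and 0.56.

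The remaining lists did not move as a whole at 2 weeks, though single members did. Of the p53 targets, 2 of 23 rose and 5 did adjusted over the list alone (adjusted p = 0.211), among them the cell death effector gene BAX (0.64 ± 0.12, 0.0102) and GDF15. Of 17 immediate early genes, NR4A1 (-0.997 ± 0.175, 0.00660) and the phosphatase genes DUSP5 (-0.82 ± 0.15, 0.00810) and DUSP1 (-0.79 ± 0.21, 0.0478) fell and IER3 rose (0.55 ± 0.14, 0.0364), against 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.252, and 0.0227 with a filter at an FPKM of 5). The lipid droplet gene PLIN2 rose (0.79 ± 0.12, 0.00228). LPCAT1, which makes surfactant phospholipid, fell by 1.01 ± 0.17 (0.00599), and so did DNMT3B, a DNA methyltransferase of interest given the title of the series (4.45 ± 0.39 to 2.502 ± 0.165 FPKM, -0.72 ± 0.17, 0.0265), while DNMT3A had a change of 0.36 (0.139). CDT1, which licenses replication, rose by 0.49 ± 0.12 (0.0378), the only called gene of 39 in the cell cycle list (median 0.08, negative under the 3 other scalings, adjusted p = 0.681), which held 0 genes adjusted over the list alone by limma. Metallothioneins (6 measured), interferon-stimulated genes (14), heat shock genes (15), glycolysis genes (15) and hypoxia targets (20) held 0 genes called by limma over all genes. Hypoxia targets held 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0876, and 0.0470 under quantile normalization). Markers of other cell types were scarce, with 2 fibroblast, 3 leukocyte and 1 endothelial gene measured and 0 called by limma over all genes in either CSC comparison. Adjusted over the list alone at 2 weeks, 1 fibroblast marker was higher (THY1, 0.56) and 1 lower (COL1A1, -0.51). Without DMSO 2 weeks replicate 3 the adjusted p rose to 0.0588 for BAX, and without CSC 2 weeks replicate 3 to 0.103 for GDF15, 0.134 for IER3 and 0.103 for DNMT3B. It was 0.138 for DUSP1 without DMSO 2 weeks replicate 1 and, without CSC 2 weeks replicate 1, 0.146 for CDT1.

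The changes at the 2 times overlapped. Both comparisons called 11 genes higher, among them CYP1B1, TIPARP, GREM1, ALDH1A3 and TMEM156, and 19 lower, among them PDE3A, RTN4RL2, NPTX1, NR4A1, SUSD2 and C1QTNF6. The comparisons have no library in common, but both took each gene's spread from the same fit. Independent lists of these lengths would share 0.391 and 0.552 genes, and the exact hypergeometric test gave p = 1.16e-15 and 7.64e-28. That test takes genes and lists as independent. The shared spread makes the same genes easier to call in both, so these p-values only describe the overlap. Others in both, picked after their values were seen, were IGFBP3, a binding protein of insulin-like growth factors, at -1.10 and -2.15, the cross-linking enzyme TGM2 at -0.91 and -1.64, and the EGF receptor ligand TGFA at 0.98 and 0.65. Only CCL2 was called in opposite directions. Of the 676 genes called at 2 weeks, 600 (88.8%) had the same sign at 48 hours, where 50.3% of all genes were positive. Across the 12506 genes the effects correlated with Pearson's r = 0.45 and Spearman's rho = 0.42, and genes are not independent replicates. The 30 shared calls became 10 without DMSO 48 hours replicate 3, 15 without DMSO 48 hours replicate 2 and 80 without CSC 48 hours replicate 3. They became 2 in fits of only the libraries compared, 18 without a filter and 56 under quantile normalization.

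**Figure D3:**
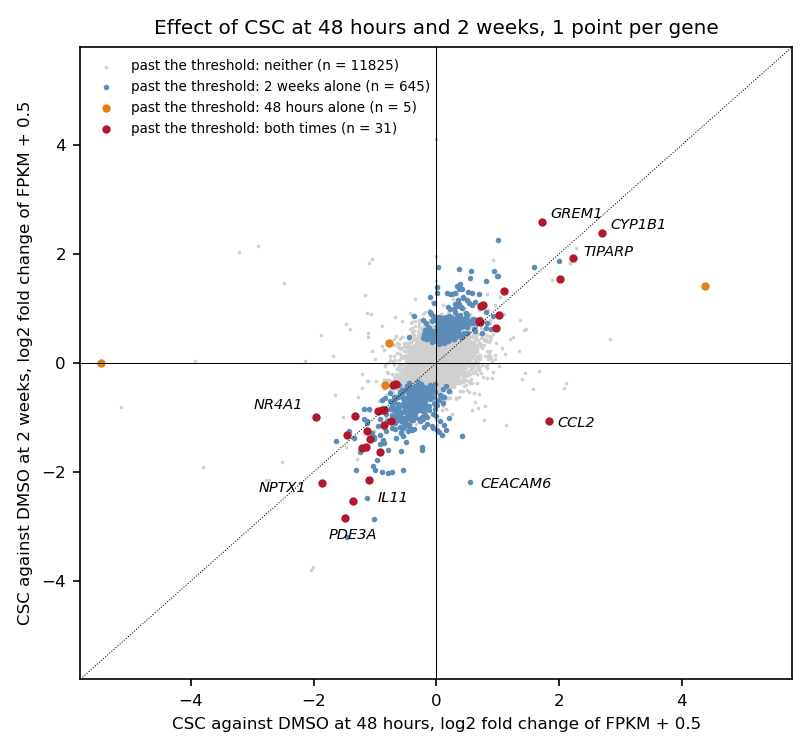
Log2 fold change of FPKM + 0.5, CSC against DMSO, at 48 hours (horizontal axis) and 2 weeks (vertical axis), 1 point per tested gene, coloured by the comparison that called it, with the diagonal of equal effects dotted. CYP1B1, TIPARP and GREM1 lie high at both times and PDE3A and NPTX1 low at both, while CCL2 is at 1.83 and -1.06.

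Which effects differed between 48 hours and 2 weeks was tested as a difference of the CSC effects, which called 4 genes lower and 1 higher. CCL2 rose at 48 hours and fell at 2 weeks, a difference of -2.89 ± 0.39 (SE, adjusted p = 0.0288 by limma). For CEACAM6 the difference was -2.73 ± 0.36 (0.0288), for GABRE, a GABA receptor subunit, -1.31 ± 0.19 (0.0383) and for RTN4RL2, which fell at both times, -1.18 ± 0.17 (0.0432). CEACAM6 was at 7.64 and 6.93 FPKM in DMSO at 48 hours and at 29.7, 30.1 and 26.1 at 2 weeks. With CSC it was at 17.6, 7.48 and 9.71, and then at 5.46, 7.57 and 4.95. GABRE went in DMSO from 7.29 and 7.87 to 11.18, 12.01 and 14.45. With CSC it went from 6.83, 5.88 and 6.47 to 3.33, 4.41 and 4.18. For CEACAM6 and GABRE the difference thus includes a rise of the DMSO level between the times. SNAR-E was the gene called higher, since it was listed at 0 in 9 libraries, and 876 genes had an unadjusted p under 0.05. The adjusted p reached 0.118 for CCL2 without CSC 2 weeks replicate 3. Without DMSO 48 hours replicate 3 it reached 0.209 for CEACAM6, 0.210 for GABRE and 0.349 for RTN4RL2. The count of higher genes ran from 0 without DMSO 48 hours replicate 2 or 3 (limma), where SNAR-E is not tested, to 6 without CSC 48 hours replicate 3, with 2 without CSC 2 weeks replicate 1. That of lower genes was 0 by limma without DMSO 48 hours replicate 3, CSC 2 weeks replicate 3 or any 1 of the 3 DMSO libraries of 2 weeks. It was 1 without CSC 48 hours replicate 1 and 2 without DMSO 48 hours replicate 2 or CSC 2 weeks replicate 2.

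By camera, 9 lists differed between the times. The CSC effect was lower at 2 weeks than at 48 hours for inflammatory genes (median difference -0.62, adjusted p = 1.13e-11). The same held for mesenchymal and matrix genes (-0.40, 1.57e-05) and immediate early genes (-0.16, 0.0106). This concerns effects and not levels. Relative to the mean of all libraries, mesenchymal medians in DMSO were 0.19 and -0.22 at 48 hours and 0.41, 0.37 and 0.31 at 2 weeks. With CSC they were -0.36, -0.22 and -0.19 at 48 hours and -0.14, 0.001 and -0.19 at 2 weeks. AHR-responsive genes were low only relative to the other genes (median -0.04, adjusted p = 0.0297), with 9 positive and 9 negative differences. The effect was higher at 2 weeks for ribosomal protein genes (0.49, 7.76e-15), NRF2 targets (0.38, 3.79e-05), histones (0.37, 0.00901), cell cycle genes (0.29, 1.04e-04) and glycolysis genes (0.29, 0.0106). These calls were lost with the correlation estimated: adjusted p = 0.208 with an estimated correlation for inflammatory genes, 0.692 for mesenchymal genes and 0.710 for the other 7. With fry all 9 were lost too, at adjusted p = 0.357 for inflammatory and ribosomal protein genes and more for the others. Under quantile normalization the median differences of the lists with a higher effect were 0.15, 0.08, 0.07, 0.16 and 0.07 in the order above. With a common sum they were 0.30, 0.19, 0.19, 0.11 and 0.10. With the preset correlation, the inflammatory, mesenchymal and ribosomal protein lists passed under each other scaling and filter and without any 1 library. CCL2 had a lower effect at 2 weeks over all genes, and so had 5 inflammatory genes adjusted over the list alone. The other 8 lists had 0 members called by limma over all genes or adjusted over the list alone.

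The other 6 differences depended on single settings, which were tried after the data were seen. NRF2 targets (adjusted p = 0.0778), histones (0.446) and glycolysis genes (0.446) did not pass under quantile normalization. Without CSC 48 hours replicate 3 the adjusted p was 0.498 for cell cycle genes, 0.227 for glycolysis genes, 0.696 for immediate early genes and 0.814 for AHR-responsive genes. Leaving out DMSO 48 hours replicate 2 gave 0.221 for histones, 0.0999 for glycolysis genes and 0.142 for AHR-responsive genes. Histones also missed the threshold without CSC 48 hours replicate 1 (0.0870), CSC 2 weeks replicate 1 (0.0873) or replicate 3 (0.141), glycolysis genes without CSC 2 weeks replicate 1 (0.0722), and AHR-responsive genes without CSC 2 weeks replicate 1 (0.142) or replicate 3 (0.0650), without a filter (0.129) and under median-of-ratios (0.0737) or common sum scaling (0.221). Immediate early genes did so without DMSO 48 hours replicate 3 (0.158) or CSC 2 weeks replicate 2 (0.144), without a filter (0.0937) and with a common sum (0.102). Heat shock genes had a median difference of 0.26 (adjusted p = 0.452) that passed upward without CSC 48 hours replicate 2 (0.00780) and downward without CSC 48 hours replicate 3 (8.82e-04). Stress response genes passed without CSC 48 hours replicate 3 (6.84e-06), and epithelial genes under quantile normalization (0.0418). Metallothioneins passed without CSC 48 hours replicate 1 (0.0396), DMSO 2 weeks replicate 3 (0.0353) or CSC 2 weeks replicate 1 (0.0297), cholesterol genes without CSC 48 hours replicate 1 (0.0389) or CSC 2 weeks replicate 3 (0.0194), and alveolar type II markers without DMSO 48 hours replicate 3 (0.0310).

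As a background, the DMSO libraries of 2 weeks were compared with those of 48 hours. The sample titles name no batch, so a difference in preparation between these groups cannot be told apart from time. Rises were found in 82 genes and falls in 14, of 12506 tested, and 1601 had an unadjusted p under 0.05. Of the largest, SLPI, an airway protease inhibitor, went from 0.602 ± 0.417 (SD, n = 2) at 48 hours to 8.76 ± 1.80 FPKM (SD, n = 3) at 2 weeks (3.11 ± 0.34, adjusted p = 7.88e-04 by limma). Neurotensin (NTS) went from 3.35 ± 0.25 to 29.0 ± 1.36 (2.94 ± 0.29, 3.98e-04). The epithelial sodium channel gene SCNN1A rose by 2.30 ± 0.21 (2.34e-04) and the siderophore-binding LCN2 by 2.69 ± 0.45 (0.0181). CXCL5 went from 62.6 ± 8.52 to 22.9 ± 1.33 (-1.42 ± 0.12, 1.61e-04), and the cholesterol exporter ABCA1 (-1.15 ± 0.14, 0.00181) and the activin antagonist FST (-1.39 ± 0.21, 0.00874) fell. HNRNPA1P10 and SNAR-E passed as well and are uncertain as above. In both genes the 2 DMSO libraries of 48 hours stood apart from all other libraries. HNRNPA1P10 was at 0.0248 and 0.00908 FPKM in them and at 3.93 or more elsewhere. Whether these libraries differ in preparation was not tested.

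Mesenchymal and matrix genes were higher at 2 weeks in DMSO (23 measured, median 0.45, adjusted p = 0.00254, and adjusted p = 0.992 with an estimated correlation), with SNAI1 called (0.90 ± 0.18, 0.0364) and 3 adjusted over the list alone. The list did not pass without DMSO 48 hours replicate 3 (adjusted p = 0.526). Of the 2 measured fibroblast markers, COL1A1, a fibrillar collagen gene, was called over all genes and adjusted over the list alone (5.12 ± 1.64 to 11.1 ± 0.61 FPKM, 1.08 ± 0.17, adjusted p = 0.0140), while THY1 had a change of 0.09 (0.902). As a list they did not pass camera (adjusted p = 0.245, and adjusted p = 0.992 with an estimated correlation; fry adjusted p = 0.0330). Inflammatory genes were lower (17 measured, median -0.04, adjusted p = 0.0383, and adjusted p = 0.992 with an estimated correlation), with CXCL5 lower over all genes and adjusted over the list alone. That call ended under each other scaling (0.135 with median of ratios, 0.0656 with a common sum, 0.217 with quantile normalization). The same held without a filter (0.0574) and with a filter at an FPKM of 5 (0.0757). It ended too without DMSO 48 hours replicate 2 (0.913), DMSO 2 weeks replicate 1 (0.0562) or replicate 2 (0.0542), or CSC 2 weeks replicate 1 (0.0503) or replicate 2 (0.0734). Cell cycle genes (main adjusted p = 0.186) passed downward under quantile normalization (0.00215), with a common sum (0.0395), with a filter at an FPKM of 5 (0.0313) and without DMSO 48 hours replicate 3 (0.0180). NRF2 targets (main adjusted p = 0.631) passed without that library as well (0.0180), and epithelial genes with a common sum (0.0395).

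With the FPKM as deposited 85.4% of the 96 calls were higher, against 72.1% under median-of-ratios scaling (44 higher, 17 lower), 70.5% with a common sum (31 and 13) and 68.3% under quantile normalization (41 and 19). Leaving out 1 library gave 20 to 185 higher and 4 to 25 lower genes: 20 and 6 without DMSO 2 weeks replicate 1 and 185 and 25 without CSC 48 hours replicate 3. Other counts of higher and lower genes were 22 and 4 without DMSO 48 hours replicate 3, 45 and 4 without DMSO 48 hours replicate 2, 27 and 4 without DMSO 2 weeks replicate 2, 32 and 4 without DMSO 2 weeks replicate 3, and 48 and 8 without CSC 2 weeks replicate 3. A fit of only the 5 libraries compared gave 232 and 28, and without a filter 38 and 4 were called. Without DMSO 48 hours replicate 3 the adjusted p rose to 0.119 for HNRNPA1P10 and 0.110 for FST, and without DMSO 48 hours replicate 2 to 0.158 for LCN2.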

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

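Of the tests in this part, those of the scaling of ribosomal protein genes, of a mixed library and of the 2 DMSO libraries at 48 hours were chosen after the result was seen, and the others were written before their values were computed. The single genes and lists below stand out because the CSC effect at 2 weeks differed from that at 48 hours by a test of the difference itself.

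CCL2, the monocyte chemokine, had a difference of -2.89 (log2, 2 weeks minus 48 hours), the adhesion molecule CEACAM6 of -2.73, the GABA receptor subunit GABRE of -1.31 and the Nogo receptor relative RTN4RL2 of -1.18. For CEACAM6 and GABRE the difference includes a rise of the DMSO level from 48 hours to 2 weeks. SNAR-E averaged 21.5 FPKM in DMSO at 48 hours and was listed at 0 in all other groups. Among lists, the median difference was -0.62 for inflammatory genes, -0.40 for mesenchymal and matrix genes, -0.16 for immediate early genes and -0.0403 for AHR-responsive genes. It was 0.49 for ribosomal protein genes, 0.38 for NRF2 targets, 0.37 for replication-dependent histones, 0.29 for cell cycle genes and 0.29 for glycolysis genes. All of these list differences were lost with the correlation between genes estimated, the lowest being adjusted p = 0.208 with an estimated correlation, for inflammatory genes.

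Ribosomal protein genes such as RPS18 and RPLP0 stood higher with CSC at 2 weeks. Their transcripts are short (median 720.5 bp against 1158 bp for all genes), so technical causes tied to length were tested. Among 10000 random lists matched on length and level, the list's median of 0.54 lay at percentile 100, while the matched lists themselves had a median of 0.27, so part of the rise may be shared by short abundant transcripts. With the length trend removed in each library, the lowest CSC library of 2 weeks stayed above the highest DMSO library by 0.198, and under the other scalings the list's median was 0.211 or more. None of these causes accounts for the whole rise, and no biological explanation beyond the CSC treatment was tested.

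Far fewer genes passed at 48 hours (36) than at 2 weeks (676). Dropping 1 DMSO library of 2 weeks, which copies the 3 against 2 design, still left 239 to 261 genes, so the missing library alone does not account for it. Both comparisons took each gene's spread from the same fit, so a wider spread at 48 hours does not enter the 48-hour test alone. The residual variance was 1.19 times as large at 48 hours, but 0.662 times without CSC 48 hours replicate 3. The spread of the CSC effects with the error taken off was 2.33 times as large at 2 weeks, and 1.45 times without that library. For the 36 genes called at 48 hours the median absolute change was 1.09 then and 1.06 in the same direction at 2 weeks. They show no larger response, but their choice at 48 hours favours large values at that time. The data are consistent with a larger response at 2 weeks, but without either DMSO library of 48 hours no spread above the error remained at 48 hours and the ratio could not be formed.

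By its median over called genes, CSC 2 weeks replicate 2 lay between the other CSC and the DMSO libraries of 2 weeks. Of 1844 genes called without it, its median position between DMSO (0) and the other CSC libraries (1) was 0.836 for 185 genes with large changes and 0.361 for 1659 with smaller ones. A share of DMSO-treated RNA in that library would put all genes at the same position, and the difference of 0.476 speaks against it as the only cause. Direction and library scale enter that difference, since the position was 0.343 for higher and 0.657 for lower genes with the FPKM as deposited. For higher and lower genes apart the difference was 0.272 and 0.384, and under the other 3 scalings 0.190 to 0.235 and 0.406 to 0.424. Each of these had a 95% bootstrap interval (over genes, taken as independent) above 0, the lowest limit being 0.073. The comparison was moved from the log2 scale, where the difference was 0.386, to the FPKM scale after the values were seen, and the split by direction and scaling was added later. Single genes could lie elsewhere than between the groups. The position of this library was 1.34 for CYP1B1, 1.25 for CYP1A1, 1.12 for GREM1, 1.02 for TIPARP and 0.953 for AHRR. Its deeper sequencing might blur weak genes alone. For called genes with a mean FPKM of at least 20 its median position was 0.330 (841 genes). Replicates 1 and 3 stood at 1.09 (91 genes) and 1.01 (65 genes), a gap of 0.684 to the lower. Each position used the genes called without that library, so the gene sets differ and the gap does not decide whether depth plays a part. No biological explanation was tested.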

How the results depend on the processing

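Of the named genes and lists, 1 reversed: the heat shock list, for the difference of the CSC effects, moved up with all libraries without passing and passed downward without CSC 48 hours replicate 3 (camera, 2.47e-04 unadjusted, and up to 0.9504 without other libraries). The balance of calls at 2 weeks turned from more higher to more lower under each other scaling. With both pseudocounts, robust estimation, a filter at an FPKM of 5 and small RNA genes or symbols at several loci left out, every count stayed within 1.5 times its value. Counts are given as higher and lower, and shared means called in the same direction at both times. The cause was not tested for the changes below unless one is named. No filter: 13 lower at 48 hours, 184 higher at 2 weeks, 3 and 0 for the difference of the CSC effects, 38 and 4 for time in DMSO, 18 shared. Median-of-ratios scaling: 20 and 35 at 48 hours, 468 lower at 2 weeks, 44 higher for time. Common sum: 20 higher at 48 hours, 487 lower at 2 weeks, 31 higher for time. Quantile normalization: 31 and 44 at 48 hours, 41 higher for time, 56 shared. No mean-variance trend: 0 lower for the difference by limma. Library weights, whose estimation did not converge, so that these counts are not relied on: 60 and 148, 3781 and 1799, 48 and 36 for the difference, 637 and 74 for time, 174 shared. Replicate number as a block: 595 higher at 2 weeks, 3 higher for the difference, 9 lower for time, with 3 list calls gained and 1 not kept. The libraries share only a number by their labels. In deviations from group means, 7 of 11 correlated best with a library of their own number, a hint from the data and not from the design. The 15 pairs with the same number had r between -0.202 and 0.311, 5 of them over 0.1. Other pairs lay between -0.222 and 0.282, nearly the same range. Fewer genes by construction remain at an absolute log2 change of at least 1 (8 and 12, 47 and 95, 39 and 6 for time, 14 shared) and at an adjusted p under 0.01 (5 and 6, 65 and 123, 0 lower for the difference, 23 and 4 for time, 10 shared, all by limma). Only the libraries compared, which leaves fewer samples to estimate the spread: 2 and 1 at 48 hours, 232 and 28 for time, 2 shared. Transcript length trend removed, added after the data were seen: 494 lower at 2 weeks, 0 higher for the difference by limma, 48 higher for time.

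Leaving out 1 library at a time gave 5 to 22 higher and 6 to 76 lower at 48 hours, 73 to 1310 and 132 to 534 at 2 weeks, 0 to 6 and 0 to 5 for the difference, 20 to 185 and 4 to 25 for time, and 10 to 80 shared. The correlation of the CSC effects ran from 0.351 to 0.452. Without a DMSO library of 48 hours, the lone library left is assumed to vary like the other groups. Of 229 results for named genes 216, 212 and 210 were unchanged under the 3 scalings, 226 and 225 with pseudocounts of 0.1 and 1, and 193 without a filter. At an FPKM of 5, 188 were unchanged, 1 lost and 6 gained a call, and the rest were not tested. Of 100 list results 97, 92 and 91 were unchanged under the scalings, 78 with an estimated correlation and 77 with fry. Depth in reads is unknown, so its limit on weakly expressed genes cannot be stated.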

Other observations

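In this part the lists of genes, the test of change over time and the test of amino acid supply genes were chosen after the result was seen, and the splits of the libraries were set before. Several called members of these lists had been seen before the lists were written, so their tests are not independent of the values. Their camera p-values were adjusted over the added lists of a comparison alone. They are therefore not on the same footing as those of the 25 lists fixed before.

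Genes of liver-type secreted proteins, which A549 cells express, were lower with CSC at 2 weeks. Of 11 measured, 10 had negative changes and 5 fell (median -1.08, camera adjusted p = 6.25e-09, and adjusted p = 0.192 with an estimated correlation). They were VTN, which encodes vitronectin (-1.90, adjusted p = 5.77e-04), FGB, the complement genes C3 (-1.08, 0.0123) and C1S (-0.93, 0.0328), and the retinol carrier RBP4 (-1.23, 0.0150). Actin cytoskeleton genes were lower as well (19 measured, 5 fell, median -0.36, adjusted p = 1.46e-08, and adjusted p = 0.192 with an estimated correlation), among them MYL9 (-1.15, 0.00118), FLNA (-0.73) and VCL (-0.62, 0.0265). Both lists were low at 48 hours too, with medians of -0.69 (adjusted p = 8.28e-07) and -0.17 (0.00228), 0 members called by limma, and adjusted p = 0.581 with an estimated correlation for both. Nuclear-encoded respiratory chain genes were all positive (36 measured, 0 called by limma, median 0.32, adjusted p = 1.67e-06, and adjusted p = 0.296 with an estimated correlation). Of 31 proteasome genes 29 were positive, with PSMC4 called (0.44, adjusted p = 0.0426), a list median of 0.25 (adjusted p = 7.49e-04) and adjusted p = 0.459 with an estimated correlation. With a common sum of FPKM these medians were 0.17 and 0.11, so that part of each rise is the shift of all genes. The random lists matched to ribosomal protein genes on length and level had medians around 0.27, mostly between 0.168 and 0.344. The respiratory chain and proteasome medians of 0.32 and 0.25 lie within that range. Neither list was compared with random lists matched to its own members, so a share tied to length and level is left open.

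Some amino acid supply genes rose at 2 weeks beside CHAC1 and ATF4, while most members of the lists below did not pass. In serine and one-carbon metabolism 5 of 14 rose (median 0.47, adjusted p = 0.00109, and adjusted p = 0.192 with an estimated correlation): PHGDH, PSAT1, MTHFD2, CBS (1.28 ± 0.27, 0.0160) and SHMT2 (0.52, 0.0235). One hypothesis is a response of the kind seen on amino acid starvation, apart from a protein folding response. It was tested with the cytosolic aminoacyl-tRNA synthetase genes, which had not been tested as a list. All 20 were positive and 5 rose, GARS (0.87 ± 0.17, 0.0125), CARS, MARS, AARS and YARS, with a median of 0.29 (0.15 with a common sum) and camera adjusted p = 1.78e-05, but adjusted p = 0.192 with an estimated correlation. No rise was found in endoplasmic reticulum chaperone genes (18 measured, 1 positive, 0 called by limma). Their median was -0.20 (camera adjusted p = 2.35e-05, and adjusted p = 0.243 with an estimated correlation). HSPA5 (-0.08 ± 0.13, adjusted p = 0.737 by limma) and HSP90B1 (-0.31 ± 0.14, 0.181) did not pass. The chaperone list was as low at 48 hours (median -0.22, adjusted p = 1.17e-04, and adjusted p = 0.581 with an estimated correlation), when the synthetase and serine lists did not pass (0.115 and 0.0755). In CSC 48 hours replicate 3 CHAC1 was at 12.8 FPKM and ASNS at 68.2. In replicates 1 and 2 CHAC1 was at 1.36 and 1.98 and ASNS at 24.5 and 27.2. Replicate 3 stood apart in other lists too, so its values do not show such a response to CSC at 48 hours. The values at 2 weeks are consistent with the hypothesis but do not show its cause, since neither amino acid levels nor protein synthesis were measured.

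Another hypothesis is that CSC opposes part of the rise of genes over time seen in DMSO. Of the 82 genes that rose over time in DMSO, such as SLPI and NTS, 78 also had a positive change over time with CSC. Their median change over time was 0.54 with CSC and 0.96 in DMSO, but their choice by the rise in DMSO favours a larger value there. Of the 82, 49 were called lower and 2 higher with CSC at 2 weeks, but these comparisons share the DMSO libraries of 2 weeks. The test therefore held out each of those libraries in turn, chose the genes from the rest, and compared CSC with the held-out library alone. The medians were -1.11, -0.80 and -0.651 (20, 27 and 32 genes), against lower 2.5% limits of -0.10, -0.06 and 0.02 for random lists. For the 14 genes that fell over time, on which this test was not run, the median CSC effect at 2 weeks was 0.09, with 3 called higher and 1 lower, and the hypothesis is left open for them. For the genes that rose, the held-out values are as the hypothesis predicts. They do not decide it, since anything shared by the 3 DMSO libraries of 2 weeks would also raise the held-out library. Whether the pattern reflects growth, density or the condensate itself was not tested.

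Other splits of the 6 libraries of 2 weeks were tried. Of the 10 ways to form groups of 3 and 3, only 1, the real one, called as many as its 676 genes, and the highest other split called 0 by limma. With 10 splits the lowest share possible is too large to serve as a test at the 0.05 level.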
